A study of Mus musculus with 24 samples.

How the data were processed

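RNA was measured in 24 libraries from LβT2 mouse gonadotrope cells. The labels give 6 groups of 4 libraries. Cells were transfected with scrambled (control) or β-catenin siRNA for 48 h, starved of serum overnight, and given vehicle or 5 nM GnRH for 45 min or 2 h. The design text states 3 samples per lane on 8 lanes but does not say which samples shared a lane, so a lane could not be entered as a factor.

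Each deposited file held raw whole-number counts per feature for 1 library, with no normalization, per the file headers and the values. The files were laid out in blocks of 1 transcript model each, with its exons and introns, so the deposited count columns also held other text on the layout lines. All 1781662 feature lines of each file were checked and held whole numbers. Dividing the counts of uniquely mapped reads by the length and by the reads in the first line gave the RPKM column of the same file. The genome build was mm9 per the submitters' processing notes. The aligner and the quantifier were not given in the sources used here.

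The files described 112463 transcript models, of which 82003 (72.9%) received a gene symbol from their RefSeq or Vega accession. They formed 25432 named genes and 5189 unnamed loci. Another 24656 models without a symbol shared exon bases with a named model and were left out. The count of a gene was that of its transcript model with the most uniquely mapped reads over all libraries. The files listed 4.34 M to 68.51 M reads per library, and 3004826 to 49261207 reads fell in genes. The lowest depths were 4.34 M reads in replicate 4 of the β-catenin siRNA 45 min group and 4.94 M in replicate 4 of the control siRNA 2 h group.

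Genes were kept with a filter on low counts (minimum count 10, minimum total 15, smallest group 4), which left 16072. Scaling used TMM factors. Counts were turned into log2 values with weights by the voom method (limma 3.58.1 in R 4.3.3, offset 0.5, lowess span 0.5). One model of 6 group means was fitted to all 24 libraries, with 18 residual degrees of freedom and robust empirical Bayes moderation. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was counted as rising or falling at an adjusted p under 0.05. The plan had named edgeR quasi-likelihood for this test and DESeq2 as an alternative, and these were not run. The block layout kept the column check from accepting the columns as counts, and limma-voom, planned as an alternative, took their place. Trial fits of the data had been seen by then. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures. Levels are counts per 1e6 (CPM) over the TMM-scaled library size, given as mean ± SD over n = 4 libraries.

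The comparisons were GnRH against vehicle at 45 min and 2 h in each of the 2 siRNA arms, β-catenin against control siRNA under each of the 3 treatments, and the 2 interactions of siRNA with GnRH, 9 in all. A total of 22 gene lists were tested with camera (limma, preset correlation 0.01 between genes). Other runs used an estimated correlation and the fry test. Camera compares a list with other genes, whereas fry tests its genes against no change. Members of a list were counted at adjusted p over all genes and over the list alone. The comparisons, the lists, the rule for naming genes and the alternatives first listed were chosen before the data were examined. The rule named 10 fixed genes and the largest rises and falls among called genes whose groups did not overlap, 10 each way for GnRH in control cells and for siRNA under vehicle, and 3 each way elsewhere. For each list it named the largest called members.

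Libraries differed in how strongly counts followed the GC content of genes. As an alternative chosen after the data were seen, a smooth trend of counts over GC content and length (loess, span 0.3) was removed from each library, which left 15542 genes with a GC value. The test and this removal were tested on simulated data made from 15567 genes, with 200 changed at 45 min of GnRH in control cells. No other comparison was simulated. With no trend, the test recovered 97% of 2-fold changes, and 3.9% of its calls were unchanged genes. With the GC trend of the real libraries it recovered 52% of 2-fold and 93% of 4-fold changes, and 7.05% of its calls were unchanged genes. With the trend removed, these were 96%, 100% and 3.92%. The simulated trend had the form that the removal itself fits, so good recovery was built in. The changed genes were drawn at random, so these rates do not cover real changes that follow GC content.

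Other alternatives were RLE and upper-quartile scaling, no filter, a minimum of 1 CPM in 4 libraries, the longest transcript model, RefSeq models alone, added non-uniquely mapped reads, limma-trend, a fit of the libraries of each contrast alone, the replicate number as a block, leaving out each library in turn, and leaving out the 2 libraries of lowest depth. RefSeq models alone, limma-trend, the 2 libraries of lowest depth and every setting with the GC trend removed were chosen after seeing the data. Intron reads were summed per gene and tested in the same way. Relations with remaining Ctnnb1 were tested with 100000 permutations within groups. The pairs of libraries within a group were checked for duplicates, and the spread per degree of freedom over genes lay between 3.01 and 308.68 times the counting error in the 36 pairs.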

Results

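The data were 24 RNA libraries of LβT2 gonadotrope cells, 4 in each of 6 groups. Cells carried control or β-catenin siRNA and received vehicle, GnRH for 45 min or GnRH for 2 h. The files listed 4.34 M to 68.51 M reads per library. The labels number the replicates within each group and do not state whether these were separate cultures, so p-values measure the spread between samples so numbered. The full fit estimated this spread over all 6 groups, so libraries outside a contrast also entered its p-value.

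The groups did not share 1 composition of reads. Genes of 60% GC or more (835 genes) took 3.85% to 4.94% of gene reads in all 8 libraries of 2 h GnRH. They took 1.64%, 1.43% and 1.54% in replicates 1 to 3 of control vehicle but 0.46% in replicate 4. Replicate 4 of the β-catenin siRNA 45 min group had 4.31%, and the remaining libraries 0.31% to 1.22%. Mitochondrial reads were 1.62% to 2.14% in the 8 libraries of 2 h and 2.3% to 4.76% in the other 16. Multimapped reads were 15.92% to 16.6% against 13.79% to 15.64%, and intron reads 26.21% to 34.05% of exon reads against 30.2% to 42.92%. The first principal component held 82.1% of the variance, and its gene weights followed GC content (Spearman 0.8, absolute). Values with the GC trend removed are therefore given beside many results.

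**Figure D1:**
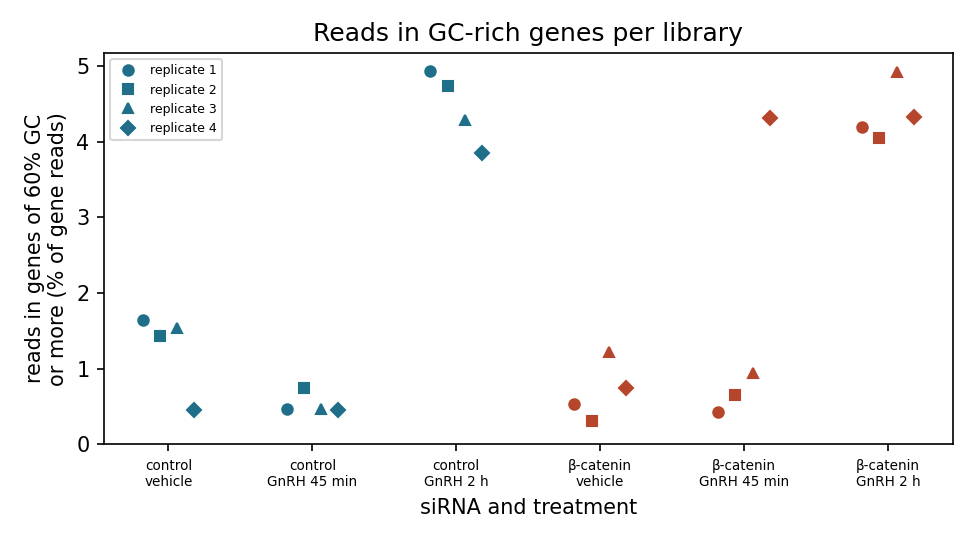
Share of gene reads in genes of 60% GC or more (y axis, percent) for the 6 groups of siRNA and treatment (x axis). Each point is 1 library, and the marker gives the replicate number. The 2 h libraries and 1 library of β-catenin siRNA at 45 min lay apart from the others.

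The first question was how far the siRNA lowered its target. Ctnnb1 (chromosome 9, 120842518 to 120869625, 15 exons) encodes β-catenin, which links cadherins to actin and carries the Wnt signal to the nucleus. Its level under vehicle was 584 ± 11.8 CPM with control siRNA and 165 ± 60.6 CPM with β-catenin siRNA (n = 4 each). At 45 min the levels were 565 ± 25.9 and 156 ± 47.8 CPM, and at 2 h they were 600.4 ± 11.5 and 184 ± 52.8 CPM. The log2 changes were -1.90, -1.97 and -1.75 (limma-voom, adjusted p = 0.00048, 0.000203 and 0.00118), and all 12 knockdown libraries lay below all 12 controls. In a fit of the 8 libraries of each contrast alone, the adjusted p was 0.531, 0.14 and 0.0022. Remaining Ctnnb1 ran from 16.5% to 40.1% of the control mean under vehicle, from 17.1% to 36.9% at 45 min and from 20.9% to 42% at 2 h. GnRH itself left exonic Ctnnb1 without a call in control cells (log2 change -0.05 and 0.04, adjusted p = 0.879 and 0.887).

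**Figure D2:**
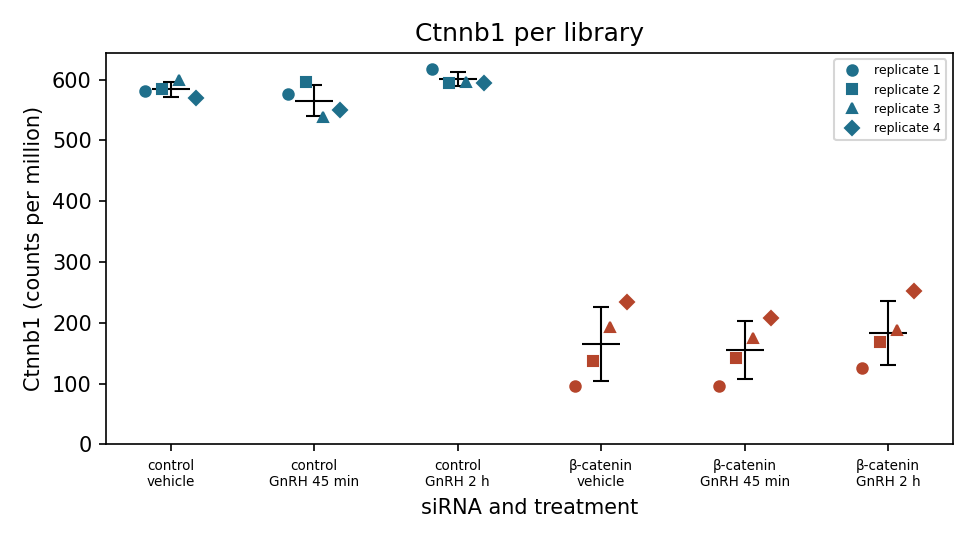
Ctnnb1 (y axis, CPM) in the 6 groups of siRNA and treatment (x axis). Points are libraries, markers give the replicate number, and bars give mean ± SD of 4 libraries. Every β-catenin siRNA library lay below every control library.

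The next question was what 45 min of GnRH changed in control cells. Immediate-early genes carried the strongest rises. Egr1 (chromosome 18, 35020861 to 35024638, 2 exons), the transcription factor through which GnRH acts on the Lhb promoter, rose from 3.23 ± 0.211 to 1590 ± 107 CPM. Fos (chromosome 12, 86814840 to 86818223, 4 exons), a subunit of AP-1, rose from 5.38 ± 0.501 to 547 ± 54.3 CPM. Jun, its partner, rose from 7.45 ± 0.293 to 174 ± 10.8 CPM, and Fosb from 1.49 ± 0.359 to 419.8 ± 44.3 CPM. Egr2 rose by 8.51 on the log2 scale, and the orphan nuclear receptors Nr4a1, Nr4a3 and Nr4a2 rose by 7.40, 7.01 and 6.89. Egr4 and Egr3, with 2 and 3 reads in the control vehicle libraries, reached 15.6 ± 1.68 and 9.03 ± 4.29 CPM. In each of these, all 4 treated libraries lay above all 4 vehicle libraries.

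Of 37 measured immediate-early genes, 34 rose at 45 min and 36 did so when adjusted over the list alone (camera, adjusted p = 5.69e-60, and 8.47e-05 with an estimated correlation). Feedback regulators of MAPK rose in 10 of 20 and fell in 1 (adjusted p = 3.57e-07, 0.00144 with an estimated correlation), led by the phosphatases Dusp5 (log2 change 4.75) and Dusp1 (3.31). Targets of SRF and actin genes rose in 8 of 17, or 11 adjusted over the list alone, with Actg1 at 2.76 (adjusted p = 1.54e-05, 0.0243 with an estimated correlation). The cAMP and CREB list had 7 rises and 2 falls among 19 (adjusted p = 0.00139, 0.00651 with an estimated correlation), with the kinase Sik1 at 4.41. Sterol synthesis had 8 rises among 19, including Idi1 (1.24), and endoplasmic reticulum stress had 7 among 20, including the chaperone Hspa5 (0.81). Their adjusted p was 0.0136 and 0.0188 (0.0243 and 0.0282 with an estimated correlation). The interferon list had 6 rises, including Cxcl10 (2.87), and 1 fall among 22 (adjusted p = 0.00467, but 0.117 with an estimated correlation). Within activin signalling, the corepressors Tgif1 (3.82) and Skil (2.07) rose, while the list as a whole had 3 rises and 3 falls among 25 (adjusted p = 0.389).

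At 45 min limma-voom called 1264 rises and 1284 falls among 16072 genes, 2548 in all. The count with the GC trend removed was 5161, of which 1922 were shared with the same sign. A fit of the 8 libraries alone called 662. Fold changes followed GC content (Spearman -0.69), and the median GC was 47.4% for genes that rose and 55.1% for genes that fell. The largest falls were of low, GC-rich genes such as Rnf208 (1.01 ± 0.596 to 0.0462 ± 0.0686 CPM), Pkdcc, Amdhd2, Rtn4r and Dact2. In the fit of the 8 libraries alone, Pkdcc, Amdhd2 and Rtn4r had adjusted p = 0.0779, 0.0881 and 0.0655. The count depended on single libraries. It was 929, 966, 957 and 9425 without control vehicle replicates 1 to 4, and 1007, 4634, 1071 and 1039 without control 45 min replicates 1 to 4. Without control vehicle replicate 4, fold changes followed GC content more closely (Spearman -0.74), and 3681 of the 9425 calls were shared with the fit that had the trend removed.

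The largest changes after 2 h of GnRH in control cells included genes little expressed under vehicle. Vgf, a granule peptide precursor (chromosome 5, 137506165 to 137509221, 2 exons), rose from 1.75 ± 0.754 to 1427 ± 274 CPM. Pcsk1n, an inhibitor of the prohormone convertase PC1, rose from 0.596 ± 0.428 to 259.8 ± 75.5 CPM. The secretory granule list as a group did not differ from other genes by camera (adjusted p = 0.307), with 9 of 27 genes raised and 6 lowered. Tested against no change by fry, its adjusted p was 4.22e-09. Of all 16072 genes 10209 were called in this comparison, so a list can pass that test without a response of its own. Rrad (chromosome 8, 107151966 to 107155221, 5 exons), a small GTPase that restrains calcium channels, rose from 0.667 ± 0.193 to 427 ± 53.2 CPM. Junb rose from 0.305 ± 0.227 to 669.7 ± 96.8 CPM, and Nr4a1 reached 2022 ± 210.0 CPM. Fos fell back from its 45 min level to 179.5 ± 10.3 CPM and Jun stood at 339.9 ± 35.7 CPM, each still above vehicle (log2 change 5.06 and 5.51). Axin2 (chromosome 11, 108781663 to 108812095), a feedback inhibitor and target of Wnt signalling, rose from 8.99 ± 1.72 to 38.7 ± 2.6 CPM (log2 change 2.12, adjusted p = 6.85e-08). The change of Axin2 was 1.69 with the GC trend removed (adjusted p = 4.59e-13). The largest falls included Zfp273, Zfp455 and other zinc finger genes, and Lmo3 (7.55 ± 1.09 to 0.749 ± 0.176 CPM). In replicate 4 of β-catenin siRNA at 45 min, which had the 2 h composition, Pcsk1n, Junb and Axin2 stood at 252, 845 and 31.2 CPM. The rest of its group had 0.152 to 0.173, 2.44 to 8.04 and 9.19 to 14.4 CPM. Composition and time of GnRH could thus not be told apart for Pcsk1n, Junb and Axin2. Rrad (13.5 CPM) and Vgf (256 CPM) in that library lay below every 2 h library of its arm. They lay above the rest of their group (2.18 to 4.02 and 3.81 to 12.9 CPM), so composition stays open for part of their rise too. Nr4a1 (3140 against 427 to 1090 CPM) and Lmo3 (3.67 against 7.52 to 8.99 CPM) also differed from that group in the 2 h direction. Fos (836 against 513 to 574 CPM) differed in the other direction.

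**Figure D3:**
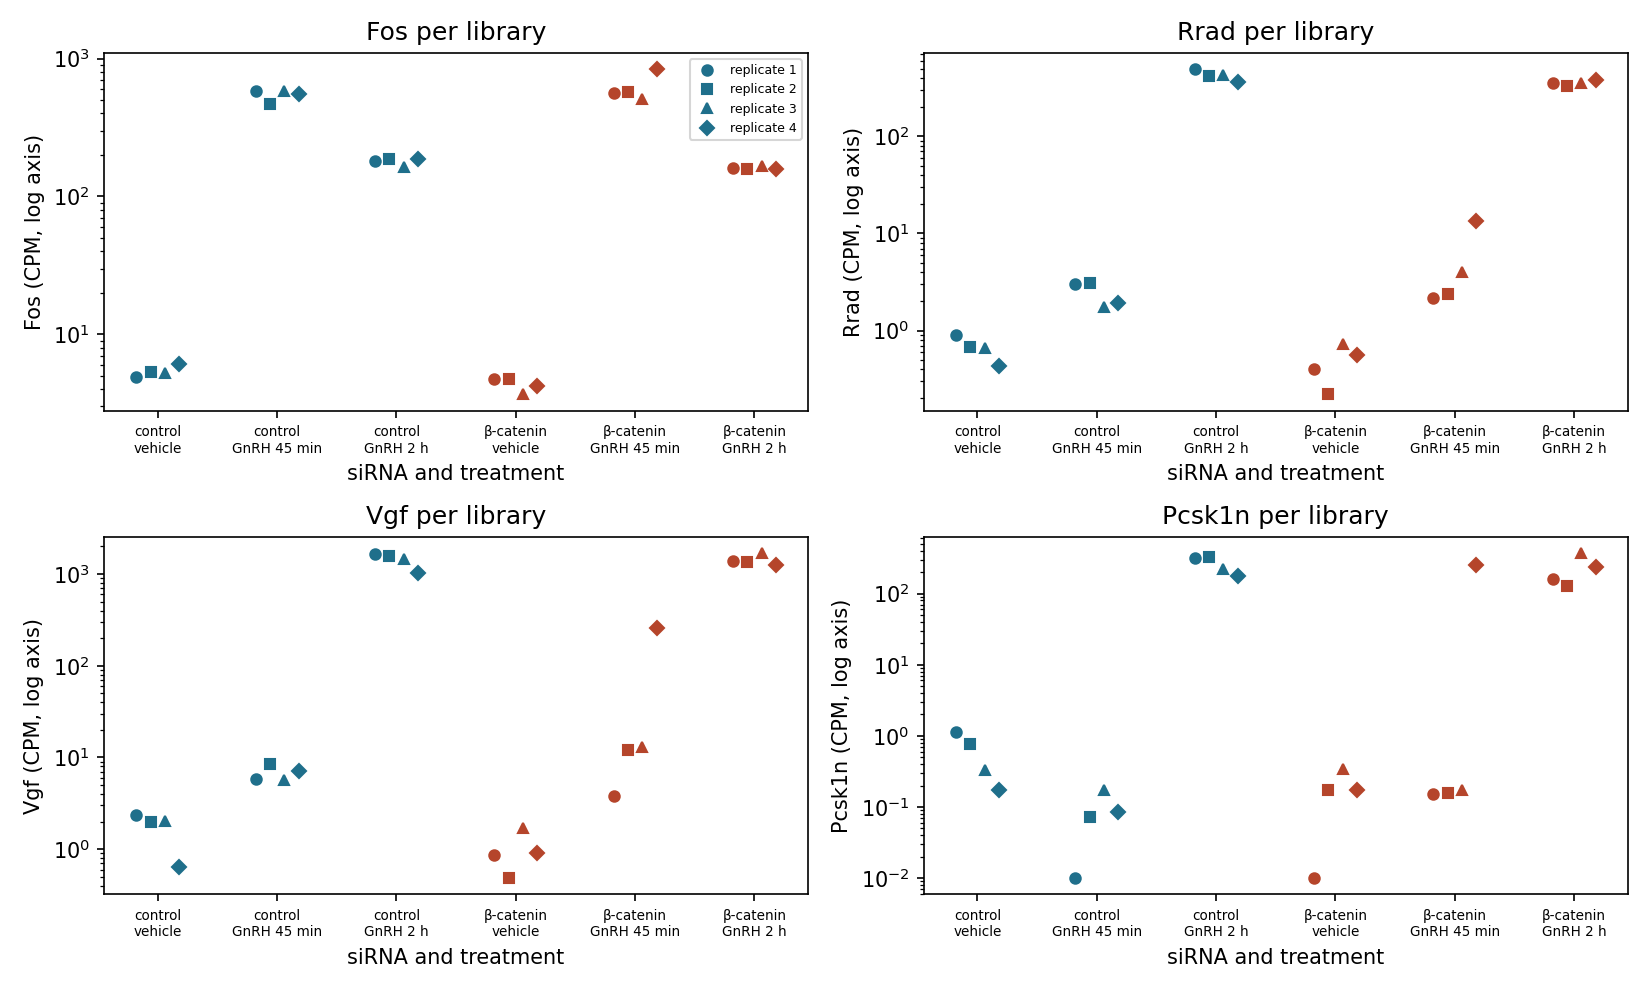
Fos, Rrad, Vgf and Pcsk1n (y axes, CPM on a log scale) in the 6 groups of siRNA and treatment (x axes). Points are libraries, and markers give the replicate number. A level of 0 is drawn at 0.01. Fos was highest at 45 min and the other 3 genes at 2 h, and replicate 4 of β-catenin siRNA at 45 min stood above its group in all 4.

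All 37 measured immediate-early genes had risen at 2 h (camera, adjusted p = 5.35e-33, 0.00132 with an estimated correlation). MAPK feedback had 17 rises and 1 fall among 20, and SRF and actin genes had 16 rises among 17, with Zyx (log2 change 6.14) and Cnn2 (5.81). Both lists had adjusted p = 2.02e-10 (0.000349 and 0.00138 with an estimated correlation). Endoplasmic reticulum stress had 15 rises and 1 fall among 20 (adjusted p = 9.17e-05, 0.00132 with an estimated correlation), among them Chac1 (3.48) and Ddit3 (2.39). The adherens junction list had 14 rises and 2 falls among 21, including Cdh1 (3.59) and Nectin2 (3.44), with adjusted p = 0.00899 (0.0147 with an estimated correlation). Heat shock had 10 rises among 14 (adjusted p = 0.0139, 0.06 with the GC trend removed), and sterol synthesis 10 rises and 1 fall among 19 (adjusted p = 0.0129). Activin signalling had 12 rises and 6 falls among 25 (adjusted p = 0.0476, 0.162 with the GC trend removed), and was lost without vehicle replicates 1 or 3 (adjusted p = 0.0507 and 0.0545) or 2 h replicate 4 (adjusted p = 0.0501). Small interfering RNA machinery fell in 7 of 10 and rose in 1 (adjusted p = 0.0402, 0.201 with an estimated correlation). Wnt targets had 7 rises and 2 falls among 15 (adjusted p = 0.145).

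The 2 h comparison in control cells called 5256 rises and 4953 falls. Its fold changes followed GC content (Spearman 0.65), and all 4 of its GnRH libraries had the GC-rich composition given above. With the GC trend removed, 6600 of these 10209 genes (64.6%) kept the call with the same sign, and 563 were called with the other sign. Lhb was among the genes whose direction depended on this. It rose from 9.53 ± 1.97 to 24.7 ± 5.0 CPM (log2 change 1.44, adjusted p = 2.42e-06), but the change was -0.77 with the trend removed (adjusted p = 0.042). Rrad changed by 9.31 and 8.01 in the 2 fits, Vgf by 9.73 and 7.0.

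The same questions were asked in cells with β-catenin siRNA. Egr1 rose from 2.30 ± 0.452 to 1539 ± 234 CPM at 45 min and 1022 ± 86.1 CPM at 2 h, and Fos from 4.35 ± 0.527 to 621 ± 146 and 161 ± 3.34 CPM. Nr4a1 rose from 1.497 ± 0.859 to 1335 ± 1230 CPM at 45 min, where replicate 4 had 3140 CPM and the other 3 had 427 to 1090 CPM. Replicate 4 also carried genes otherwise seen at 2 h. It had 252 CPM of Pcsk1n against 0.152 to 0.173 CPM in the rest of its group, and 845 CPM of Junb against 2.44 to 8.04 CPM. Med18, a subunit of the Mediator complex, fell from 9.17 ± 0.595 to 3.15 ± 0.603 CPM at 45 min (log2 change -1.47, adjusted p = 9.59e-07). Axin2 rose by 0.92 at 45 min (adjusted p = 0.0348), and by 2.34 at 2 h (adjusted p = 1.62e-08). The 45 min call for Axin2 was lost without vehicle replicates 1, 2 or 4 (adjusted p = 0.0687, 0.126 and 0.0947) or 45 min replicates 3 or 4 (adjusted p = 0.11 and 0.0568).

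In these knockdown cells 37 of 37 immediate-early genes rose at 45 min and 36 at 2 h (camera, adjusted p = 1.47e-102 and 3.01e-24). MAPK feedback and SRF and actin genes each rose in 10 at 45 min, of 20 and 17. Lists of cAMP response (6 of 19), sterol synthesis (3 of 19), endoplasmic reticulum stress (3 of 20) and activin signalling (3 of 25) also rose at 45 min. Adjusted over the list alone the last 3 had 7, 7 and 5 rises. Their adjusted p was 0.000198, 0.000257, 0.000441 and 0.00411. At 2 h the adherens junction list had 14 rises and 3 falls (adjusted p = 0.0291, 0.0358 with an estimated correlation). The heat shock and sterol lists passed narrowly (adjusted p = 0.0496 each, 0.0666 with an estimated correlation). Small interfering RNA machinery fell in 8 of 10 and rose in 2 at 2 h (adjusted p = 0.0496, 0.242 with an estimated correlation). A list of blood, endothelial, fibroblast and immune markers had 2 rises among 7 at 45 min and 5 at 2 h (adjusted p = 0.0345 and 0.0496, but 0.245 and 0.242 with an estimated correlation). In all, 612 rises and 219 falls were called at 45 min and 6427 and 5806 at 2 h. With the GC trend removed the totals of 831 and 12233 became 2184 and 10621. At 2 h 6940 genes (56.7%) kept their sign and 1620 were called with the other sign. Across genes the GnRH effects of the 2 siRNA arms had a Spearman correlation of -0.02 at 45 min (0.41 with the trend removed) and 0.96 at 2 h. The Pearson correlation at 45 min was 0.33 (0.61 with the trend removed).

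Whether β-catenin siRNA changed other genes was asked first under vehicle. Nnt, the mitochondrial transhydrogenase that makes NADPH (chromosome 13, 120124255 to 120197804, 17 exons), fell from 71.2 ± 3.6 to 40.5 ± 3.84 CPM (log2 change -0.81, adjusted p = 9.61e-05). The groups did not overlap, and the call held without any 1 of the 8 libraries (highest adjusted p = 0.000942). Nqo1, a quinone reductase, rose from 19.8 ± 2.72 to 30.6 ± 3.66 CPM (log2 change 0.62, adjusted p = 0.0371). The Nqo1 call was lost without control replicates 1, 2 or 3 (adjusted p = 0.144, 0.176 and 0.167) or knockdown replicates 1, 2 or 4 (adjusted p = 0.115, 0.102 and 0.0863). The kallikrein Klk7 fell from 17.1 ± 1.63 to 10.3 ± 0.756 CPM (-0.72, adjusted p = 0.0171). The call for Klk7 was lost without control replicate 3 (adjusted p = 0.0722) or knockdown replicates 1, 2 or 4 (adjusted p = 0.0556, 0.0536 and 0.0863). No fixed list was called. Wnt targets had 0 calls among 15 (camera, adjusted p = 0.854), the lowest adjusted p was 0.126, and Axin2 changed by -0.36 (adjusted p = 0.334).

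Under vehicle limma-voom called 7 rises and 12 falls after siRNA, 2715 genes had an unadjusted p under 0.05, and 891 genes were called with the GC trend removed. A fit of the 8 libraries alone called 0. Leaving out control vehicle replicates 1 to 4 gave 3, 6, 2 and 6399 genes, and leaving out knockdown vehicle replicates 1 to 4 gave 3, 3, 54 and 2. The 6399 followed GC content (Spearman -0.79), and 574 of them were shared with the fit that had the trend removed.

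At 45 min of GnRH the siRNA lowered 40 genes and raised 6. Plk2, a polo-like kinase induced early by growth signals (chromosome 13, 111185252 to 111191051, 14 exons), fell from 100.6 ± 7.06 to 62.6 ± 8.38 CPM (log2 change -0.66, adjusted p = 0.0103). This call was lost without control replicate 1 (adjusted p = 0.0604) or knockdown replicates 2 or 3 (adjusted p = 0.0503 and 0.0868). The potassium channel Kcnj16 fell from 6.5 ± 1.08 to 1.95 ± 0.486 CPM (-1.62, adjusted p = 0.00365, kept without any 1 library). Oasl2, an interferon target, fell by 0.51 (adjusted p = 0.0264). It lost its call without control replicates 1, 3 or 4 (adjusted p = 0.12, 0.0978 and 0.0944) or knockdown replicates 2 or 3 (adjusted p = 0.097 and 0.116). The interferon list moved down as a group (camera, adjusted p = 0.00841, but 0.277 with an estimated correlation), with 1 of 22 members called and 4 adjusted over the list alone. Without control 45 min replicate 2 its adjusted p was 0.058. The p53 list was not called (adjusted p = 0.0526), but passed without control replicates 1, 3 or 4 (adjusted p = 0.0379, 0.04 and 0.0329) or knockdown replicate 4 (adjusted p = 0.000342). The 46 calls became 485 with the GC trend removed and 0 in a fit of the 8 libraries alone, where 1333 had been the count at an unadjusted p under 0.05 in the full fit. Leaving out control replicates 1, 3 or 4 gave 16, 28 or 27 calls, and knockdown replicates 1, 2 or 3 gave 98, 18 or 14.

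At 2 h of GnRH the siRNA lowered 22 genes and raised 3. Plk2 was again lower, at 51.6 ± 3.21 against 86.2 ± 3.85 CPM (log2 change -0.75, adjusted p = 0.0063, kept without any 1 library). Psg16 fell from 3.87 ± 0.246 to 1.45 ± 0.115 CPM (-1.39, adjusted p = 3.44e-05, kept without any 1 library). Tgif1, a corepressor of SMAD signalling, fell from 19.7 ± 1.86 to 11.9 ± 1.2 CPM (-0.73, adjusted p = 0.0158). The call for Tgif1 was lost without control replicates 1 or 2 (adjusted p = 0.132 and 0.0813) or knockdown replicates 2 or 3 (adjusted p = 0.0992 and 0.0559). Sec16b, of endoplasmic reticulum exit sites, rose from 12.8 ± 1.86 to 22.6 ± 0.513 CPM (0.76, adjusted p = 0.0155). The call for Sec16b was lost without the same 4 libraries (adjusted p = 0.0666, 0.0813, 0.066 and 0.0559). The p53 list moved down as a group, with 0 of 15 members called over all genes and 3 adjusted over the list alone (camera, adjusted p = 2.51e-05, 0.00134 with an estimated correlation). The activin list also moved down (adjusted p = 0.00403, 0.013 with an estimated correlation, 0.114 by fry). Immediate-early genes did so with adjusted p = 0.000512 (0.399 with an estimated correlation), and Plk2 was the 1 member called. Wnt targets again had 0 calls (adjusted p = 0.376). The 25 calls became 683 with the GC trend removed and 1127 in a fit of the 8 libraries alone, whose 2 groups shared 1 composition. Without control replicates 1 or 2 they were 6 or 7, and without knockdown replicates 2 or 3 they were 13 or 9.

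The siRNA effects at different treatments share no libraries and can be compared. All 19 genes called under vehicle moved the same way at 45 min and at 2 h, 10 and 8 of them with a call. All 46 genes called at 45 min moved the same way at 2 h, 15 with a call. Over all genes the Spearman correlations were -0.54 (vehicle with 45 min), 0.27 (vehicle with 2 h) and 0.12 (45 min with 2 h), and -0.16, 0.30 and 0.27 with the GC trend removed.

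The study's title names Fshb and Brms1l, which were followed through every group. Fshb (chromosome 2, 106896297 to 106899813, 3 exons) encodes the β subunit of follicle-stimulating hormone and was low throughout. In control cells it stood at 2.06 ± 0.494 CPM under vehicle, 4.81 ± 0.303 at 45 min and 3.80 ± 1.03 at 2 h. With β-catenin siRNA the levels were 1.45 ± 0.369, 1.87 ± 1.12 and 2.04 ± 0.228 CPM. In control cells Fshb rose by 1.26 at 45 min (adjusted p = 0.0015) and by 0.78 at 2 h (adjusted p = 0.0101), with all 4 treated above all 4 vehicle libraries each time, and both calls held without any 1 library. These rises were 0.91 and 1.24 with the GC trend removed. In knockdown cells the changes were 0.52 and 0.58 (adjusted p = 0.515 and 0.0563), and 0.60 and 1.26 with the GC trend removed (adjusted p = 0.0855 and 7.87e-06). The 2 h change was called without vehicle replicate 4 of that arm (adjusted p = 0.0344). The interactions, which test whether the response differed between the siRNA arms, were -0.74 and -0.20 on the log2 scale and were not called (adjusted p = 0.202 and 0.773). They were -0.31 and 0.03 with the GC trend removed (adjusted p = 0.533 and 0.977).

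Set against control siRNA at the same treatment, Fshb changed by -0.56 under vehicle, -1.30 at 45 min and -0.76 at 2 h (adjusted p = 0.287, 0.0398 and 0.463). The 45 min call rested on few libraries. It was lost without control replicates 1 to 4 in turn (adjusted p = 0.1, 0.0669, 0.109 and 0.118), without knockdown replicates 3 or 4 (adjusted p = 0.319 and 0.0583) and in a fit of the 8 libraries alone (adjusted p = 0.659), though all 4 knockdown libraries lay below all 4 controls. The 2 h change was called in a fit of its 8 libraries alone (adjusted p = 0.0126). With the GC trend removed, the 3 changes were -0.79, -1.11 and -0.77 (adjusted p = 0.0212, 0.00181 and 0.00934).

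Brms1l (chromosome 12, 56937353 to 56970722, 10 exons) encodes a subunit of the SIN3 and HDAC corepressor complex. In control cells it stood at 100 ± 25.7 CPM under vehicle, 124 ± 7.56 at 45 min and 48.7 ± 3.33 at 2 h. With β-catenin siRNA it stood at 93.2 ± 16.8, 81.7 ± 14.7 and 39.0 ± 1.64 CPM. Brms1l was lower after 2 h of GnRH than under vehicle in both arms (log2 change -0.99 and -1.24, adjusted p = 1.02e-05 and 3.7e-07, and -0.47 and -0.52 with the GC trend removed). In the 45 min knockdown library with the 2 h composition it had 61.1 CPM, against 81.9 to 95.1 CPM in the rest of that group and 36.8 to 40.5 CPM at 2 h. Composition and time of GnRH could thus not be told apart for part of this fall. The 45 min change in control cells was 0.34 (adjusted p = 0.0792), and 0.05 with the GC trend removed (adjusted p = 0.395). It was 0.50 without control vehicle replicate 4 (adjusted p = 0.00317), which had 138 CPM, but fold changes in that setting followed GC content (Spearman -0.74). The siRNA changed Brms1l by -0.09, -0.56 and -0.33 under vehicle, at 45 min and at 2 h, none of them called in the full fit (adjusted p = 0.66, 0.147 and 0.947). The 2 h change was called in a fit of its 8 libraries alone (adjusted p = 0.00566). With the GC trend removed, these were -0.30, -0.40 and -0.35 and all 3 were called (adjusted p = 0.000491, 8.69e-05 and 0.000988). The interactions were -0.47 and -0.24 (adjusted p = 0.202 and 0.672), and -0.09 and -0.05 with the GC trend removed (adjusted p = 0.452 and 0.838). The first was called without control vehicle replicate 4 (adjusted p = 0.0328). In that setting 6774 genes were called for this interaction, and the changes followed GC content (Spearman 0.82), so this call could not be told apart from composition.

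**Figure D4:**
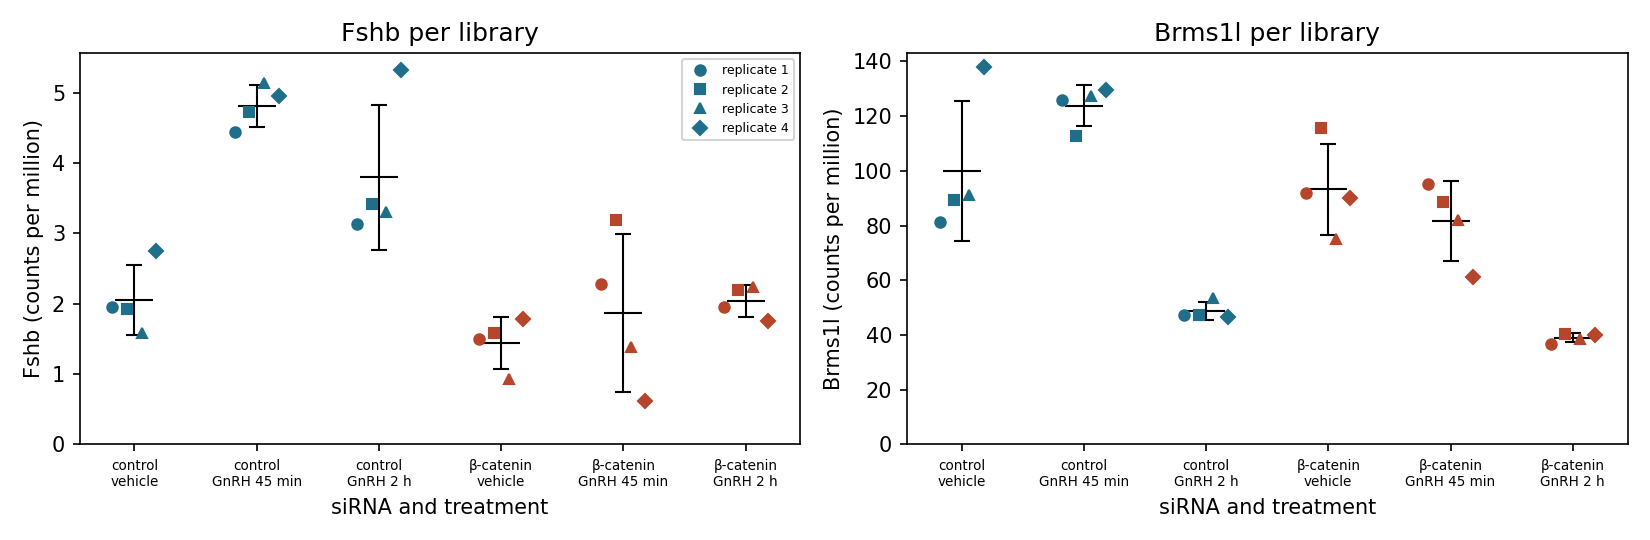
Fshb and Brms1l (y axes, CPM) in the 6 groups of siRNA and treatment (x axes). Points are libraries, markers give the replicate number, and bars give mean ± SD of 4 libraries. Fshb in control cells was higher in every GnRH library than in any vehicle library, and Brms1l was lowest at 2 h in both siRNA arms.

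Other genes of the gonadotrope were read in the same way. Cga, the α subunit shared by the gonadotropins, stood at 3321 ± 499 CPM under vehicle and 4143 ± 438 at 45 min in control cells (log2 change 0.32, adjusted p = 0.0719, and 0.15 with the GC trend removed, adjusted p = 0.128). The rise of Cga passed without control vehicle replicate 4 (adjusted p = 0.0102) or 45 min replicate 2 (adjusted p = 0.041). Gnrhr, the receptor for GnRH, stood at 1410 ± 493 and 2011 ± 259 CPM (0.56, adjusted p = 0.104, and 0.17 with the GC trend removed, adjusted p = 0.00489). It stood at 941 ± 77.6 CPM after 2 h (-0.53, adjusted p = 0.0749, but a rise of 0.205 and adjusted p = 0.000527 with the GC trend removed). Without control vehicle replicate 4, which had 2149 CPM of Gnrhr, the 45 min change was 0.78 (adjusted p = 0.013). Fold changes without that library followed GC content (Spearman -0.74), so the values of Cga and Gnrhr there could not be told apart from composition. In knockdown cells Gnrhr fell at 2 h by 0.87 (adjusted p = 0.0049), but the change was 0.21 with the GC trend removed. Across the gonadotrope list at 2 h in control cells 7 genes rose, among them Pitx1 (4.41, but 1.25 with the GC trend removed), and 5 fell among 19 (camera, adjusted p = 0.568). In the 45 min knockdown library with the 2 h composition Pitx1 had 412 CPM, against 2.04 to 5.53 CPM in the rest of that group.

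The last question was whether the response to GnRH differed between the siRNA arms for any gene. The interaction of siRNA with GnRH had 0 calls at 45 min and 0 at 2 h by limma-voom. The counts at an unadjusted p under 0.05 were 3871 and 443 of 16072 genes, and with the GC trend removed 2 and 3 genes were called. Without control vehicle replicate 4, 6774 genes were called at 45 min. Their changes followed GC content (Spearman 0.82), and 1 of them was shared with the fit that had the trend removed. Among the lists, immediate-early genes had the 1 interaction called at 45 min, upward (camera, adjusted p = 0.0349, but 0.846 with an estimated correlation). Replicate 4 of β-catenin siRNA at 45 min, with the 2 h composition, stood far above its group in several members. These were Egr4 (684 against 14.7 to 27 CPM), Junb (845 against 2.44 to 8.04) and Jun (1000 against 163 to 183). Nr4a3 (422 against 459 to 682) and Plk2 (54.1 against 58.4 to 73.5) lay below it.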

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

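The removal of the GC trend, the tests of the 2 h pattern and the test of the order of remaining Ctnnb1 against chance were chosen after the results were seen. A library was taken as standing apart when its gap to the nearest of its group was over Dixon's 95% limit. Of 84 groups of 4 tested in this way 13 passed, where chance gives about 1 in 20, or 4.2.

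Replicate 4 of the β-catenin siRNA 45 min group stood apart in 4 measures. It had 4.34 M reads in its file (33.2 M to 38.9 M in the other 3), 4.31% of reads in GC-rich genes (0.43% to 0.94%), 1890 CPM of Egr1 (1380 to 1460) and 1000 CPM of Jun (163 to 183). Replicate 4 of control vehicle stood apart in 3. It had 2150 CPM of Gnrhr (1140 to 1200), 6.41 CPM of Axin2 (9.79 to 9.9) and 4.21% mitochondrial reads (2.4% to 2.52%). The other 6 were spread over libraries. Control 2 h replicate 1 had 618 CPM of Ctnnb1 (594 to 596), replicate 3 had 53.7 CPM of Brms1l (46.6 to 47.3) and replicate 4 had 5.33 CPM of Fshb (3.14 to 3.41). Control 45 min replicate 2 had 3490 CPM of Cga (4330 to 4420) and 0.74% of reads in GC-rich genes (0.46% to 0.47%). Replicate 3 of β-catenin siRNA at 2 h had 166 CPM of Fos (159 to 160). Intron reads, which the comparisons of the report did not use, rose in 3664 genes at 45 min of GnRH in control cells.

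The first pattern weighed was the large number of genes called at 2 h. A smooth trend over GC content and length did not account for all calls in control cells, since 64.6% kept their sign and call once it was removed. The bounds for this test were set after the results, and the removal cannot take off gene-level effects of the same library profile. Pcsk1n kept a change of 7.94 with the trend removed, yet had 252 CPM in the 45 min library that carried the 2 h profile. The test thus cannot decide on the profile as a cause. A profile of the library, apart from the time of GnRH, could explain part in knockdown cells. Replicate 4 of β-catenin siRNA at 45 min had the GC profile of the 2 h libraries and lay nearer the 2 h mean than its own group for 68.8% of the 12233 called genes. It was not a mislabelled 2 h library, since its Rrad lay 4.63 below the lowest 2 h library on the log2 scale. Because all 8 libraries of 2 h carried this profile, a difference in library preparation and a biological effect of 2 h of GnRH stay open for most single genes.

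The second pattern was the small number of genes called after siRNA under vehicle. Leaving out the 2 libraries of lowest depth gave 53 genes against 19, but those 2 belong to other groups, so the count is no test of depth under vehicle. Whether depth limited these calls stays open. Spread along the GC trend was tested by the correlation of siRNA effects under vehicle and at 2 h, which rose by 0.03 once the trend was removed, below the 0.1 set beforehand. That bound was about the order of fold changes and not their spread, and 891 genes were called with the trend removed, so this explanation stays open. No biological explanation was tested.

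The third pattern was the order of the knockdown. Remaining Ctnnb1 ranked the replicate numbers 1 to 4 alike in all 3 knockdown groups, and the exact share of orderings as concordant is 0.00174, which argues against a chance order. The depth of knockdown may have followed something that the replicate number marks, such as a shared transfection. The 682 other genes called after siRNA at 2 h with the GC trend removed showed no relation to it within groups (Pearson r = 0.19 over 12 libraries, permutation p = 0.631). What the number marks stays open.

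Other splits of the same libraries were counted for each comparison. For GnRH at 2 h in control cells the real split called 10209 genes and the highest other 5249 (1 of 35 splits as large). In knockdown cells these were 12233 and 4349 (1 of 35). For siRNA they were 46 and 0 at 45 min and 25 and 0 at 2 h, each 1 of 35, with Ctnnb1 among the calls. A share of 1 of 35 is the lowest that 35 splits can give, and it was not adjusted over the comparisons. It argues against chance but does not exclude it, and calls that follow library composition count in it too. For GnRH at 45 min another split called more genes in control cells (2548 against 10008, 2 of 35). In knockdown cells (831 against 8334, 3 of 35) and for siRNA under vehicle (19 against 10895, 3 of 35) the same held. Splits that call several times the real count point to a structure among these libraries, so chance stays open for these counts. The count does not speak for single genes. Egr1 and Fos, fixed beforehand, rose at 45 min by 8.94 and 6.67 in control cells (limma-voom, adjusted p = 4.25e-21 and 2.77e-18). In knockdown cells they rose by 9.38 and 7.16 (adjusted p = 4.93e-21 and 1.23e-18). No treated library overlapped vehicle, which argues against chance for these genes. With the trend removed, the real and highest other counts for GnRH were 5161 and 6188 (2 of 35) and 2184 and 3257 (2 of 35) at 45 min. They were 9964 and 6027 (1 of 35) and 10621 and 1058 (1 of 35) at 2 h. For siRNA they were 891 and 6336 (2 of 35), 485 and 38 (1 of 35), and 683 and 10 (1 of 35). So the real split called the most genes in the same comparisons as before. The interactions called 0, which all 100 drawn splits reached, with highest others of 9600 and 11142.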

How the results depend on the processing

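Settings with the GC trend removed, RefSeq models alone, limma-trend and the removal of the 2 libraries of lowest depth were chosen after the data were seen. The planned DESeq2 test was not run. Direction reversed in no setting that kept the GC trend. With it removed, the log2 changes below had the opposite sign, in the order trend removed, with the replicate block, and within the contrast alone. At 45 min in control cells these were Lhb 1.24, 1.26 and 1.25, Inhbb 0.71, 0.69 and 0.73, Dusp7 0.48, 0.44 and 0.48, and Suds3 0.39, 0.38 and 0.38. At 2 h in control cells they were Lhb -0.77, -0.74 and -0.72, Gnrhr 0.20, 0.20 and 0.21, Rasa2 0.089, 0.093 and 0.1, Dnajc3 0.25, 0.26 and 0.26, and Brms1 -0.014 and -0.038 in the first 2. At 2 h in knockdown cells they were Lhb -1.67, -1.81 and -1.69, Gnrhr 0.21, 0.21 and 0.21, Rasa2 0.18, 0.18 and 0.18, Spred1 0.32, 0.32 and 0.33, Dnajc3 0.30, 0.30 and 0.30, Atf6 0.32, 0.32 and 0.32, Hsph1 0.135, 0.134 and 0.138, and Stard4 0.32, 0.32 and 0.32. Ppp3cb (0 and 0.005) and Calm3 (-0.002) crossed 0 in the last settings. The cause was not tested.

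Counts that moved by over 1.5 times were these. GnRH at 45 min in control cells (2548) gave 1413 with no filter, 662 within the contrast, 1634 with the replicate block, 1331 with limma-trend, 4298 without the 2 libraries of lowest depth, and 5161, 4811 (block) and 4070 (contrast) with the trend removed. In knockdown cells (831) they were 230 within the contrast, and 2184 and 2091 (block) with the trend removed. SiRNA under vehicle (19) gave 2 with no filter, 0 within the contrast, 3 with the block, 5 with limma-trend, 3 with RefSeq models, 53 without the 2 libraries, and 891, 668 (block) and 72 (contrast) with the trend removed. SiRNA at 45 min (46) gave 26 with no filter, 0 within the contrast, and 485 and 496 (block) with the trend removed. SiRNA at 2 h (25) gave 1127 within the contrast, 14 with the block, 15 with limma-trend, 39 without the 2 libraries, and 683, 605 (block) and 2108 (contrast) with the trend removed. The interactions (0 and 0) gave 2 and 3 with the trend removed, and the second gave 1 within the contrast with the trend removed. The gene list tests called 38 list results over all comparisons, and 72 with fry. The cause was not tested.

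Counts for GnRH at 2 h stayed within 1.5 times, with the block 9859 and 12024. The block gave 750 for GnRH at 45 min in knockdown cells, 35 for siRNA at 45 min and 0 for both interactions. The replicate numbers were not taken as pairs, since 21 of 60 pairs correlated over 0.1 and 3 of 24 libraries correlated best with their own number (4 with the trend removed). Remaining Ctnnb1 did follow the number. Between knockdown vehicle and knockdown 45 min all 4 numbers correlated positively (0.29 to 0.69, and 0.24 to 0.42 with the trend removed). Against knockdown 2 h the correlations of these 2 groups were -0.08 to 0.21. The main fit did not take up a unit shared within that arm. With the block, adjusted p was 0.0697 for Fshb and 0.056 for Oasl2 (siRNA, 45 min), and 0.0943 for Nqo1 and 0.0943 for Klk7 (siRNA, vehicle). It was 0.0527 for Tgif1 and 0.0507 for Sec16b (siRNA, 2 h), and 0.0545 for Rtn4r (GnRH at 45 min, control cells). Leaving out 1 library at a time gave these ranges in the order of the 9 comparisons: 929 to 9425, 8974 to 10176, 612 to 930, 11345 to 12655, 2 to 6399, 14 to 98, 6 to 23, 0 to 6774, and 0 to 0, and 29 to 44 for the lists. RLE scaling left 789 of 801 results on their side of the threshold, and upper quartile 592 of 603. Without the 2 libraries of lowest depth 586 of 600 stayed, and the call for Fshb after siRNA at 45 min was lost (-1.12). Fshb had 0.611 CPM in the library of 4.34 M reads, the lowest of its group, and 5.33 CPM in that of 4.94 M reads, the highest of its group.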

Other observations

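Intron reads can show transcripts not yet spliced, but here they may also hold exons of other models of the gene. They were read apart from exons, with limma-voom on 14274 genes. Cga, whose exonic level had no call at 45 min, had intron reads of 1430 ± 150 CPM under vehicle and 3680 ± 180 CPM at 45 min in control cells (log2 change 1.36, adjusted p = 8.55e-11). They stood at 1230 ± 75.4 CPM at 2 h (-0.22, adjusted p = 0.0623). Gnrhr introns rose by 0.49 at 45 min (adjusted p = 0.000397). Brms1l introns went down at 45 min, from 138 ± 13.3 to 88.8 ± 6.8 CPM in control cells (-0.63, adjusted p = 2.8e-06) and by 0.80 in knockdown cells (adjusted p = 2.02e-07), before the exonic fall at 2 h. Ctnnb1 introns rose at 2 h from 73.9 ± 2.68 to 146 ± 7.11 CPM in control cells (0.99, adjusted p = 4.29e-10), with exonic reads at a change of 0.04. Axin2 introns rose by 1.37 at 45 min (adjusted p = 0.000135). Lhb introns rose from 0.865 ± 0.176 to 10.1 ± 2.6 CPM at 2 h in control cells (3.63, adjusted p = 8.84e-09). The GC trend was not removed from intron reads.

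After β-catenin siRNA, introns of Ctnnb1 changed by -0.13, -0.23 and -0.23 under the 3 treatments (adjusted p = 0.481, 0.436 and 0.534), where exons fell by 1.90, 1.97 and 1.75. Introns of Brms1l changed by 0.14, -0.03 and 0.05 (adjusted p = 0.487, 0.98 and 1). Over all genes, intron reads were called for 7174 and 9792 genes after GnRH in control cells (45 min and 2 h) and for 6080 and 10354 in knockdown cells. The siRNA called 15, 52 and 33 genes. The interactions called 1 and 0 genes.

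A hypothesis set before its result was seen was that libraries with more remaining Ctnnb1 would hold more Brms1l and Fshb within the knockdown groups. It was tested over 12 libraries by permutation within groups, with p adjusted over 3 relations. Brms1l had Pearson r = 0.61 (adjusted permutation p = 0.206), which fell to 0.3 without the 2 libraries farthest from the line, and Fshb had r = -0.17 (adjusted permutation p = 0.671). Neither relation passed the test.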
